A study of Arabidopsis thaliana with 16 samples.

How the data were processed

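The samples were roots of 6-day-old Arabidopsis thaliana seedlings of the Columbia ecotype, each divided into 4 longitudinal zones. Seedlings had grown for 5 days on standard medium at pH 5.7 and then for 24 h on fresh medium at pH 4.6 or pH 5.7. Both transfer media held the same salts, sucrose, agar and DMG, a buffer, so the contrast at transfer was pH alone. Each zone and pH had 2 replicates, which gave 8 groups and 16 arrays. The zones are numbered, and the labels do not say which tissue each number covers beyond calling them developmental stages. The labels do not say that the replicates came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

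Per the labels' protocols, total RNA was purified on Qiagen columns and turned into biotin-labelled cRNA by the Affymetrix protocol with 2 rounds of amplification. MAS5 was named in the submitters' processing notes; its version and settings are not given in the sources used here. The deposited table held 1 linear intensity per probe set and array, 22810 probe sets in all. The mean of the deposited intensities between the 2nd and the 98th percentile was 250.0 on every array, so the authors had scaled each array to a common target. No detection call was used here. The median intensity of an array lay between 64.7 and 101 and its first quartile between 15.6 and 38.4. Replicates correlated across tested probe sets with Pearson r from 0.838 (zone 3 at pH 5.7) to 0.958 (zone 4 at pH 4.6); probe sets are not independent replicates. No pair of replicates shared more than 1 identical value, so all 16 arrays were counted. The number of arrays limits the precision of every comparison.

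The 64 control probe sets were left out. A platform annotation table gave 13513 probe sets a single gene and 503 several genes; 8730 probe sets are not listed in it and were tested without a name. Names were updated through Entrez identifiers and the RefSeq table of assembly TAIR10.1, which held 13436 of the single-gene probe sets. Where a gene had several probe sets, the one with the highest mean over the 16 arrays stood for it. No coordinates are given, since no genome build is named for the table.

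Intensities were analysed as log2(value + 16), where 16 is a pseudocount that holds down the noise of dim probe sets; a log2 fold change on this scale understates the change of dim probe sets. Probe sets entered the tests when the mean of at least 1 zone reached the 40th percentile, 5.95 on that scale, which left 16405. Of these, 9129 stood for a named gene and 7225 had no single gene name. No further normalization between arrays was applied. A linear model with 8 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend; 8 residual and 7.44 prior degrees of freedom). The contrasts were pH 4.6 against pH 5.7 in each zone, the mean of those 4 effects, their interaction with zone (a moderated F-test on 3 contrasts), and each zone against the one before it at pH 5.7. Tests were two-sided, with Benjamini-Hochberg adjustment over the 16405 probe sets and a threshold of 0.05. Values are given as log2 fold change ± SE of this fit, with n = 2 arrays per group throughout. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so no gene was tested that way.

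Of 37 gene lists, 25 were written before the data were examined, as were the contrasts, the model, the threshold, the filter, the rule for named genes and the alternatives, except for those named in the closing part as added. The other 12 lists were gene families and organelle genomes, added after the annotation table was seen. They were fixed before the values of their members were seen, except for 1 value of a mitochondrial gene. In all 22 lists had at least 3 tested members. Some stood for a small part of the list as written. Tested were 3 of 18 proton pumps and antiporters, 3 of 31 cell division genes and 5 of 18 root hair genes. So were 4 of 20 photosynthesis genes and 4 of 24 iron deficiency genes. Statements on these lists cover the tested members only. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the 22 lists within each contrast. Of the 176 combinations of list and contrast, 37 passed with the preset correlation and 0 with the estimated one (21 at unadjusted p under 0.05). Among the low pH contrasts, directional fry called the root hair list in zone 3 (adjusted p = 0.0261), zone 4 (0.0122) and the mean effect (0.0195). It also called cell division (0.022) and photosynthesis (0.0195) in the mean effect, and photosynthesis and flavonoid synthesis in zone 1 (0.046 each). It called no organelle, ribosomal or peroxidase list in those contrasts. The list of genes that depend on STOP1, a transcription factor of proton tolerance, had no tested member and was not analysed here, like the lists for biochemical pH control, phosphate, nitrogen, phloem, jasmonate and water channels.

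Named genes followed a fixed rule over genes with their own probe set. For each zone these were the 8 largest rises and the 8 largest falls past the threshold with both arrays of 1 pH above both of the other. For the mean effect they were the 12 largest each way with the same sign in all 4 zones. For the interaction they were the 10 lowest p-values, for each zone step the 6 largest changes each way, and for each list up to 4 members with the lowest p.

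The fit was tested on simulated data, in 5 runs of 200 changed among 16405 probe sets. Both pH values had the real zone means at pH 5.7. Noise was normal, independent between probe sets, with the fitted spread of each probe set on all arrays. The real arrays were unequal, with array weights from 0.395 (zone 3 at pH 5.7) to 1.74 (zone 1 at pH 5.7), so the shares below may be too favourable. For a change in zone 3 alone, 7.46% of changes of 1 log2 unit, 62.4% of those of 2 and 93.3% of those of 3 were recovered, and 6.39% of calls were false. For the mean of 4 zones the shares were 65.4%, 100% and 100%, with 5.15% false calls. For the interaction they were 0.597%, 20.6% and 66.7%, with 7.91% false calls. Alternatives covered the pseudocount, the filter, quantile normalization and median centring, the intensity trend, array weights, replicate blocks, fits of 4 arrays alone and the removal of each array in turn. The labels do not say whether replicate numbers pair the arrays, so the fits with a replicate block stand among the alternatives. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.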

Results

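The series measured transcript levels along the Arabidopsis root, in 4 longitudinal zones, after 24 h on medium at pH 4.6 or at pH 5.7. Its title and design set out the question of how stages of root development respond to low pH. The 16 arrays form 8 groups of 2, and levels are MAS5 signal intensities. Zone differences at pH 5.7 come first, because they show what each numbered zone expressed, and then the low pH effect as a mean over zones, by zone, and as a difference between zones.

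At pH 5.7 zone 1 differed from zone 2 by rises and falls of similar number, and the largest change of a named gene was a fall. AT1G50060 fell by 7.49 ± 0.55 on the log2 scale from zone 1 to zone 2, and falls followed in AT3G19430 (-5.41 ± 0.59), AT1G52070 (-4.59 ± 0.54) and the jacalin-related lectin gene JAL33 (AT3G16450; -4.54 ± 0.28). BBM, a transcription factor of embryonic and stem cell identity, fell by 2.41 ± 0.61. Of 41 tested class III peroxidases, enzymes that act on the cell wall, 8 rose and 1 fell, led by AT3G01190 (4.66 ± 0.65) and AT2G18980 (3.65 ± 0.55); 11 rose and 5 fell adjusted over the list alone. Of the 23 expansin and XTH family members, which loosen or remodel cell walls, 0 passed the limma test over all genes, with 5 higher and 1 lower at unadjusted p under 0.05, and 4 and 1 adjusted over the list alone. In all 272 probe sets rose and 243 fell. Camera placed both wall lists higher in zone 2 (adjusted p = 0.0216 and 0.00832), but not with an estimated correlation (adjusted p = 0.593 and 0.227). The plastid list was also called higher (57 of 69 members, adjusted p = 0.0353, and 0.771 with an estimated correlation), and zone 2 replicate 2 had a plastid mean of 9.75 against 8.21 in replicate 1 and a first quartile of 30.4 against 17.7. All 12 genes ranked here had both arrays of 1 zone above both arrays of the other. Each of the 4 arrays moved the count by more than 1.5 times when left out, to between 123 and 338, and the balance turned with them: 252 were higher and 86 lower without zone 1 replicate 1, 38 higher and 85 lower without zone 1 replicate 2.

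From zone 2 to zone 3 transcripts for protein synthesis fell and those of root hairs rose. Of 111 cytosolic ribosomal protein genes 107 fell, with a median of -2.29; AT1G15250, a ribosomal protein of the L37 family, fell by 4.64 ± 0.34. Of 7 core histone genes 4 fell, among them HTB1 (-2.01 ± 0.29) and HTB4 (-2.13 ± 0.35). Of 5 root hair genes 4 rose: the peroxidases AT1G30870 (7.87 ± 0.65) and AT4G26010 (6.89 ± 0.53) and the expansins EXPA7 (5.28 ± 0.61) and EXPA18, both known from root hair cells. Of the 41 peroxidases 20 rose and 5 fell, led by AT5G66390 (7.69 ± 0.82), and 6 of 9 extensins, structural wall proteins, rose. AT4G13580, of the dirigent family, rose by 7.50 ± 0.72 and AT1G30750 by 7.37 ± 0.67. GSO1, a receptor kinase needed for the endodermal barrier, rose by 3.93 ± 0.39. All 4 tested genes of the photosynthetic machinery also rose (LHCB4.1 by 2.56 ± 0.37). Among the SWEET sugar transporters 4 of 11 rose, and 3 of 7 CYP71B cytochromes P450. This step changed the most probe sets of the 3 steps, 2231 higher and 2777 lower. The ribosomal list passed camera at adjusted p = 3.07e-42 and the root hair list at 2.51e-05; with an estimated correlation the adjusted p was 0.0803 and 0.0911.

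From zone 3 to zone 4 all tested root hair genes and some expansin and XTH genes fell. All 5 root hair genes fell, among them EXPA7 (-3.95 ± 0.61) and AT1G30870 (-3.48 ± 0.65), with 9 of 23 expansin and XTH members, such as XTH21 (fell by 4.42 ± 0.69) and XTH19 (fell by 3.59 ± 0.68). AT2G23540, of the GDSL lipase family, rose by 6.39 ± 0.42, AT4G38080 by 5.72 ± 0.43, AT5G09480 by 5.62 ± 0.41, OCT1 (AT1G73220), an organic cation transporter, by 5.28 ± 0.51, the peroxidase AT2G35380 by 5.25 ± 0.48 and AT2G22510 by 5.18 ± 0.37. In the low-oxygen list 2 of 4 genes rose, the fermentation gene PDC2 (2.73 ± 0.50) and AT4G17260 (2.02 ± 0.40), the other 2 had negative values, and 1 of those was lower adjusted over the list alone. Of 18 trichome birefringence-like genes 5 fell here; from zone 1 to zone 2, 2 had risen, and from zone 2 to zone 3, 7 had risen and 3 had fallen. In all 1088 probe sets rose and 873 fell. Camera called the root hair list at adjusted p = 0.0001 and the expansin and XTH families at 0.000441 (adjusted p = 0.144 for each with an estimated correlation). It also called the plastid list (67 of 69 lower, mean -1.21, adjusted p = 7.29e-06) and the mitochondrial list (14 of 14 lower, mean -1.17, adjusted p = 0.00142); with an estimated correlation the adjusted p was 0.749 and 0.563. Zone 3 replicate 2 had a plastid mean of 10.31 against 7.76 in replicate 1 and a first quartile of 38.4 against 19.6. The log2 ratio of 3' to 5' signal, a measure of RNA quality, also moved with this step. For GAPDH it was 5.08 and 5.59 in zone 3 against 3.25 and 3.65 in zone 4. For ubiquitin it was 3.07 and 3.34 against 2.26 and 2.55, and for actin it did not separate the zones. Without zone 3 replicate 1 the count was 3541, and without zone 3 replicate 2, zone 4 replicate 1 or zone 4 replicate 2 it was 1278, 629 or 1102.

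Averaged over the 4 zones, the ranked rises at low pH included 2 enzymes of carbon metabolism. ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle, rose by 2.57 ± 0.19 and FDH (AT5G14780), a formate dehydrogenase, by 2.12 ± 0.27. AT3G28510, an AAA-type ATPase, rose most of these (2.75 ± 0.32), and AT2G21640, known to respond to mitochondrial dysfunction, by 2.02 ± 0.26. The receptor kinase gene AT1G51830 rose by 2.03 ± 0.20, the protease AT1G66180 by 1.86 ± 0.20, ATC (AT2G27550) by 1.82 ± 0.21, AT1G63750, of the TIR-NBS-LRR class of disease resistance genes, by 1.73 ± 0.22 and AT1G60610 by 1.64 ± 0.15. The largest falls were in AT4G22640 (fell by 2.98 ± 0.24), AT4G29270 (fell by 2.17 ± 0.25), AT4G29690 (fell by 2.11 ± 0.27), AT5G23840 (fell by 2.01 ± 0.21) and AT4G22212 (fell by 1.91 ± 0.21). The dirigent family gene AT4G11210 fell by 1.69 ± 0.27 and the calmodulin-like gene AT1G76640 fell by 1.61 ± 0.31. The rule took only genes with the same sign in all 4 zones, so that trait of these 16 is no result. Of the 24 genes ranked, 4 also passed the interaction test. Among them were AT1G51830 (adjusted p = 0.00293), AT1G66180 (0.0158) and AT4G22640 (0.02).

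Among the gene lists, 3 of 5 root hair genes fell in the mean effect, namely AT4G26010 (-1.25 ± 0.27), EXPA18 (-1.14 ± 0.31) and EXPA7 (-1.12 ± 0.30), and all 5 fell adjusted over the list alone. The 5 genes had mean values of 0.06, 0.53, -2.08 and -2.29 in zones 1 to 4; no test compared the list between zones, and of its members only EXPA18 (adjusted p = 0.0437) and AT4G26010 (0.0459) passed the interaction test. Without the 4 arrays whose plastid mean lay over 1 log2 unit above that of their own replicate, AT4G26010, EXPA18 and EXPA7 had mean effects of -1.20, -0.72 and -0.60 and lost their calls there and in zones 3 and 4. That fit compares 1 array with 1 in zone 3, so a lost call there does not show a missing effect. Of 3 cell division genes AUR2, an Aurora kinase, fell by 0.76 ± 0.20, and all 3 fell adjusted over the list alone. Of 41 peroxidases 4 rose, such as AT4G33420 (1.44 ± 0.16), and 4 fell, such as AT3G49960 (fell by 1.35 ± 0.26). Of 38 glycosyltransferases 3 rose and UGT84A1 fell by 1.30 ± 0.34. Both CYP71B6 (0.94 ± 0.17) and CYP71B26 (0.79 ± 0.15) rose, out of 7 tested, and GSTU26, 1 of 10 tau glutathione S-transferases, fell by 1.01 ± 0.20. AT3G13610, an enzyme of coumarin synthesis in the iron deficiency list, rose by 0.95 ± 0.20, and the other 3 members of that list did not pass. Of the organelle genomes 2 of 69 plastid and 1 of 14 mitochondrial genes rose, as did 3 of 111 ribosomal protein genes, and the photosynthesis gene PSBW fell by 0.87 ± 0.21.

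Some lists had no limma call over all genes in the mean effect. Among them were the proton pumps and antiporters, with 0 of the 3 tested out of 18 listed (VHA-A2 -0.35 ± 0.15). Also without a call were auxin response (0 of 8), low-oxygen response (0 of 4), flavonoid synthesis (0 of 3), and stem cell niche and root cap (0 of 3). The others were extensins (0 of 9), the earlier list of expansins and xyloglucan endotransglucosylases (0 of 6), trichome birefringence-like genes (0 of 18), SWEET transporters (0 of 11) and core histones (0 of 7). At unadjusted p under 0.05 these lists had 0 to 2 members each.

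In this mean effect 601 probe sets rose and 394 fell, and 675 of those 995 had the same sign in all 4 zones (425 higher, 250 lower). At least 2-fold changes made up 317 of the 995. Camera called the root hair list (adjusted p = 0.00013) and the cell division list (adjusted p = 0.0173); with an estimated correlation the adjusted p was 0.308 and 0.347. All 24 genes ranked by the rule, from which the 16 above were taken, kept their call without any 1 array. With each array centred on its median, 291 probe sets were higher and 292 lower, and arrays from zones 1, 2, 3 and 4 each lowered the count by more than 1.5 times when left out: 593 without zone 1 pH 5.7 replicate 1, 589 without zone 2 pH 4.6 replicate 1, 640 without zone 3 pH 4.6 replicate 2, and 511 and 566 without zone 4 pH 4.6 replicates 1 and 2.

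**Figure D1:**
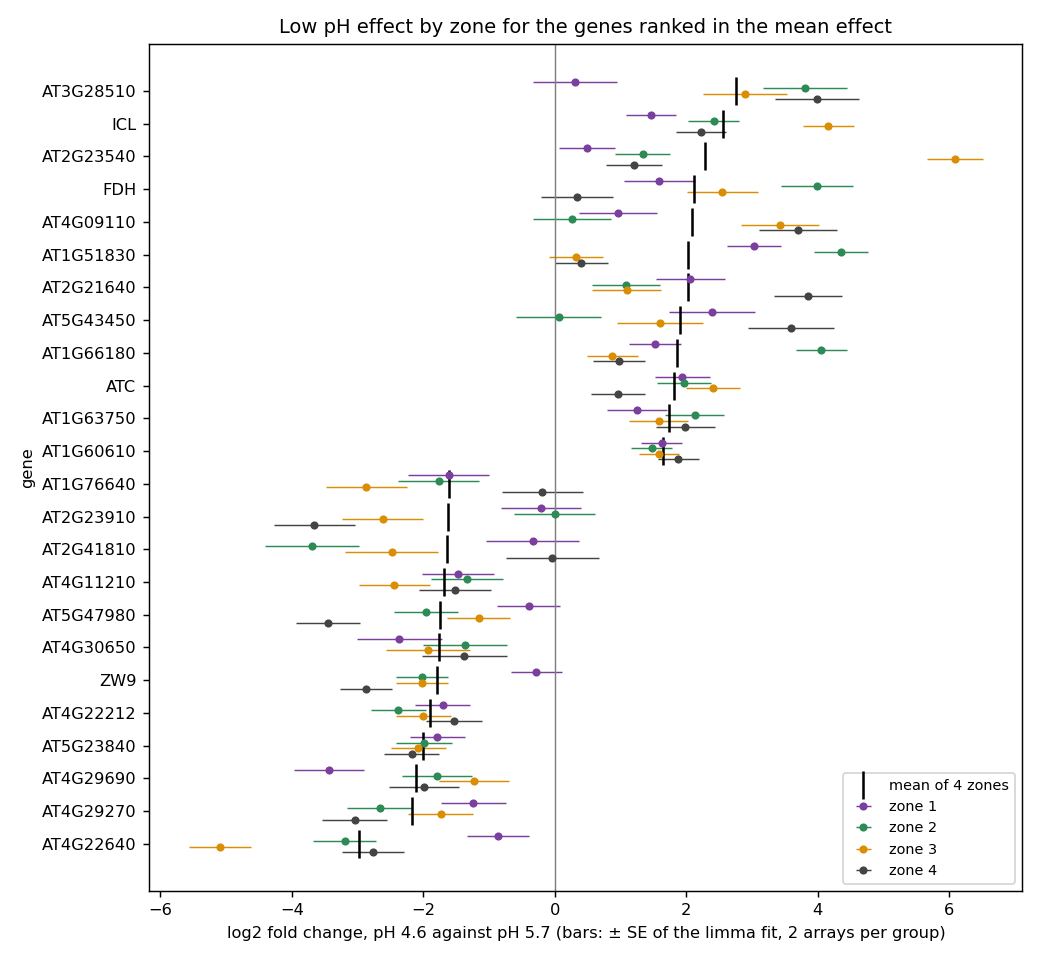
Log2 fold change of pH 4.6 against pH 5.7 for the 24 genes ranked in the mean effect; points are the 4 zones with ± SE of the fit (2 arrays per group) and the black tick is the mean of the zones. AT1G60610 (1.64) and AT5G23840 (-2.01) changed by about the same amount in each zone, whereas AT2G23540 reached 6.09 in zone 3.

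In zone 1 the largest ranked changes at low pH went both ways. AT1G78780 rose by 3.27 ± 0.64, the receptor kinase AT1G51830 by 3.03 ± 0.41, the GDSL lipase AT1G28600 by 2.85 ± 0.39, NDB3 (AT4G21490), an alternative mitochondrial NAD(P)H dehydrogenase, by 2.80 ± 0.42 and AT5G09570, known to respond to mitochondrial dysfunction, by 2.54 ± 0.56. GH9B6 (AT1G23210), a glycosyl hydrolase of family 9, fell by 3.76 ± 0.53, and falls followed in AT3G19430 (-3.59 ± 0.59), AT4G29690 (-3.43 ± 0.53), AT5G16250 (-3.40 ± 0.31), AT5G62340 (-3.33 ± 0.69), AT3G06460 (-3.29 ± 0.69), AT3G02640 (-2.94 ± 0.47) and AT4G14270 (-2.77 ± 0.45). In the iron list AT3G13610 rose by 2.02 ± 0.40.

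All 69 plastid-encoded and all 14 mitochondrion-encoded genes had higher values at pH 4.6 in zone 1, by means of 1.58 and 1.19, though 0 of either passed the limma test over all genes (28 and 5 at unadjusted p under 0.05). Adjusted over the list alone, 2 plastid and 0 mitochondrial genes were higher. Camera called both lists (adjusted p = 1.4e-17 and 3.82e-06); with an estimated correlation the adjusted p was 0.616 and 0.588. The arrays of this group also had raised low signals, with first quartiles of 27.4 and 25.8, higher than both arrays of zone 1 at pH 5.7. Their log2 ratio of 3' to 5' signal for GAPDH was 7.99 and 5.77, against 4.95 and 5.59 at pH 5.7. Those for actin and ubiquitin did not separate the 2 pH values. In all 50 probe sets rose and 62 fell in zone 1. Only AT1G51830, AT1G28600 and AT5G16250 of the 16 ranked genes kept their call without any 1 array, and the count was 36, 309, 33 and 66 without pH 4.6 replicates 1 and 2 and pH 5.7 replicates 1 and 2; with median centring 20 were higher and 41 lower.

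In zone 2 the low pH changes were mostly rises. AT1G51830 rose by 4.36 ± 0.41, the protease AT1G66180 by 4.06 ± 0.39, FDH by 3.99 ± 0.54, the peroxidase AT4G33420 by 3.93 ± 0.31, the cysteine protease CP1 (AT4G36880) by 3.90 ± 0.42 and AT3G28510 by 3.81 ± 0.64. AT1G05340 (3.53 ± 0.53) and AT1G11330 (2.96 ± 0.58) followed. AT2G41810 fell by 3.70 ± 0.71, with smaller falls in AT4G22640 (-3.20 ± 0.47), AT4G29270 (-2.67 ± 0.49), AT4G22212 (-2.38 ± 0.42), AT5G23830 (-2.03 ± 0.31) and AT1G52050 (-2.01 ± 0.40). ACLA-2 (AT1G60810), a subunit of ATP-citrate lyase, fell by 1.45 ± 0.27. Ribosomal protein genes had lower values in 104 of 111 members, with a mean of -0.43, and core histones in 7 of 7, with a mean of -0.67, but 0 of either passed the limma test over all genes (20 and 2 lower at unadjusted p under 0.05); adjusted over the list alone 2 histones fell.

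Camera called the ribosomal (adjusted p = 7.07e-12), histone (0.00622) and plastid (1.04e-06) lists lower and the glycosyltransferases higher (0.00919) in zone 2; with an estimated correlation the adjusted p was 0.848, 0.848, 0.913 and 0.848. Within this comparison zone 2 pH 5.7 replicate 2 had a plastid mean of 9.75 against 8.21 in its replicate and a first quartile of 30.4 against 17.7. In all 49 probe sets rose and 14 fell. The calls of AT1G51830, AT1G66180, AT4G33420 and CP1 held without any 1 array and those of the other 12 ranked genes did not; the count was 15 without pH 4.6 replicate 2, and 29 and 19 without pH 5.7 replicates 1 and 2.

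In zone 3 low pH raised 5 genes that were also far higher in zone 4 than in zone 3 at pH 5.7, and lowered 3 root hair genes. AT2G23540 rose by 6.09 ± 0.42, AT5G09480 by 5.17 ± 0.41, AT4G38080 by 5.04 ± 0.43, AT2G22510 by 4.69 ± 0.37 and the peroxidase AT2G35380 by 4.57 ± 0.48; these 5 genes were also 5 of the 6 largest rises from zone 3 to zone 4, a comparison that shares the zone 3 arrays at pH 5.7. AT1G49960 rose by 4.47 ± 0.50, ICL by 4.16 ± 0.38, and AT5G49350 by 3.99 ± 0.49, and UGT72E1, a glucosyltransferase of lignin precursors, also rose. AT4G22640 fell by 5.09 ± 0.47, with smaller falls in AT3G18450 (-3.66 ± 0.54), the peroxidase AT3G49960 (-3.52 ± 0.52), AT4G33730 (-3.48 ± 0.47) and AT3G53980 (-3.40 ± 0.44). Of 5 root hair genes 3 fell: EXPA18 (-2.74 ± 0.61), EXPA7 (-2.62 ± 0.61) and AT4G26010 (-2.27 ± 0.53); 4 fell adjusted over the list alone. GSTU28 fell by 3.19 ± 0.44, and 3 of 41 peroxidases rose and 2 fell, or 6 and 6 adjusted over the list alone. Of 4 photosynthesis genes PSBW fell by 1.62 ± 0.41.

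In zone 3, 312 probe sets rose and 147 fell. The log2 ratio of 3' to 5' signal was lower at low pH for GAPDH, with 4.13 and 4.44 against 5.08 and 5.59 at pH 5.7. For ubiquitin it was 2.90 and 2.92 against 3.07 and 3.34, and for actin it did not separate the 2 pH values. Camera called the root hair list lower (adjusted p = 2.02e-05) and the expansin and XTH families lower (0.0433), whose called members were EXPA18, EXPA7 and EXLB1; with an estimated correlation the adjusted p was 0.208 and 0.396. Of the 16 ranked genes 14 kept their call without any 1 array, while the count was 93 and 122 without pH 4.6 replicates 1 and 2 and 1550 and 243 without pH 5.7 replicates 1 and 2.

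In zone 4 low pH lowered 6 of 41 peroxidases and raised 2, and other large changes went both ways. AT4G13580 of the dirigent family fell by 5.22 ± 0.72, and falls followed in AT1G71740 (-4.99 ± 0.49), AT1G30750 (-4.86 ± 0.67), AT4G02090 (-4.79 ± 0.85), the glucosyltransferase UGT84A1 (-4.31 ± 0.68), the dirigent gene AT2G39430 (-4.10 ± 0.59) and AT1G72230 (-3.94 ± 0.59). Of 41 peroxidases 6 fell, such as AT1G44970 (fell by 4.04 ± 0.67), AT2G37130 (fell by 3.84 ± 0.63) and AT4G36430 (fell by 3.68 ± 0.38), and 2 rose, among them AT1G49570 (3.75 ± 0.59); adjusted over the list alone 11 fell and 3 rose. AT1G73120 rose by 6.22 ± 0.65, AT3G61930 by 5.16 ± 0.53, AT1G55430 by 4.43 ± 0.75, AT2G41730 by 4.25 ± 0.57, AT1G26250 by 4.13 ± 0.75, AT1G55390 by 4.08 ± 0.53, AT3G28510 by 3.99 ± 0.64 and AT2G21640 by 3.85 ± 0.52. Of 5 root hair genes 3 fell, namely AT4G26010 (-2.99 ± 0.53), EXPA18 (-2.90 ± 0.61) and EXPA7 (-2.36 ± 0.61), and all 5 adjusted over the list alone. Of 9 extensins AT1G26250 rose, AT3G28550 fell by 2.49 ± 0.49 and 8 had negative values; 1 was higher and 2 lower adjusted over the list alone. In the flavonoid list UGT78D2 fell by 1.74 ± 0.37. Of 111 ribosomal protein genes 6 rose, such as AT2G32220 (1.67 ± 0.34), and 98 had higher values, with a mean of 0.52; 21 rose adjusted over the list alone.

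In zone 4, 226 probe sets rose and 251 fell. Camera called the root hair list lower (adjusted p = 2.3e-07), the peroxidases lower (0.00213) and the ribosomal list higher (4.44e-09); with an estimated correlation the adjusted p was 0.104, 0.6 and 0.6. Of 3 RNA-quality measures 2 moved with pH in zone 4. The log2 ratio of 3' to 5' signal was 5.67 and 4.92 at pH 4.6 against 3.25 and 3.65 at pH 5.7 for GAPDH. For ubiquitin it was 3.24 and 2.76 against 2.26 and 2.55. For actin it did not separate, with 4.85 and 5.29 against 4.99 and 5.17. Zone 4 pH 5.7 replicates 1 and 2 had plastid means of 7.21 and 8.45 and first quartiles of 15.6 and 24.3. Of the 16 ranked genes 11 kept their call without any 1 array, while the count was 66 and 140 without pH 4.6 replicates 1 and 2 and 134 and 151 without pH 5.7 replicates 1 and 2; with median centring 130 were higher and 230 lower.

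The low pH effect differed between zones for 261 probe sets, by the moderated F-test of the interaction. JAL33 (adjusted p = 0.000235) fell by 2.06 in zone 1 and fell by 2.58 in zone 4, and rose by 1.75 in zone 3. The peroxidase AT4G36430 fell by 3.68 in zone 4 and had values of 0.31, 1.03 and 1.33 in zones 1 to 3. AT2G22510, AT2G23540, AT5G09480 and AT4G38080 rose in zone 3, by 4.69 to 6.09, and passed the test in no other zone. AT5G16250 fell by 3.40 in zone 1, AT1G71740 fell by 4.99 in zone 4, AT4G33420 rose by 3.93 in zone 2 and AT3G61930 rose by 5.16 in zone 4. At the other end, AT1G60610 had interaction adjusted p = 0.916 and AT5G23840 0.964, with log2 changes of 1.47 to 1.88 and -2.18 to -1.79 over the zones; a p that misses the threshold does not show equal effects.

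Few probe sets passed the test in several zones: 890 in 1 zone, 94 in 2, 11 in 3 and 0 in all 4. Between zones 3 and 4, which share no array, 20 probe sets were higher in both and 31 lower in both, against 4.3 and 2.25 for independent lists, and 11 moved in opposite directions. Between zones 1 and 2, 9 were higher in both and 3 lower, against 0.149 and 0.0529. All zones share the fitted spread of each probe set, so the counts for independent lists are a low baseline. Correlations of the effects across tested probe sets, which are not independent replicates, ran from -0.07 (zones 1 and 3) to 0.18 (zones 1 and 4). The count of 261 was 1142 without zone 3 pH 5.7 replicate 1 and 527 without zone 1 pH 4.6 replicate 2; it was 156 without zone 2 pH 4.6 replicate 2, 95 and 115 without zone 3 pH 4.6 replicates 1 and 2, and 77, 109, 105 and 122 without the arrays of zone 4 in the same order of pH and replicate.

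**Figure D2:**
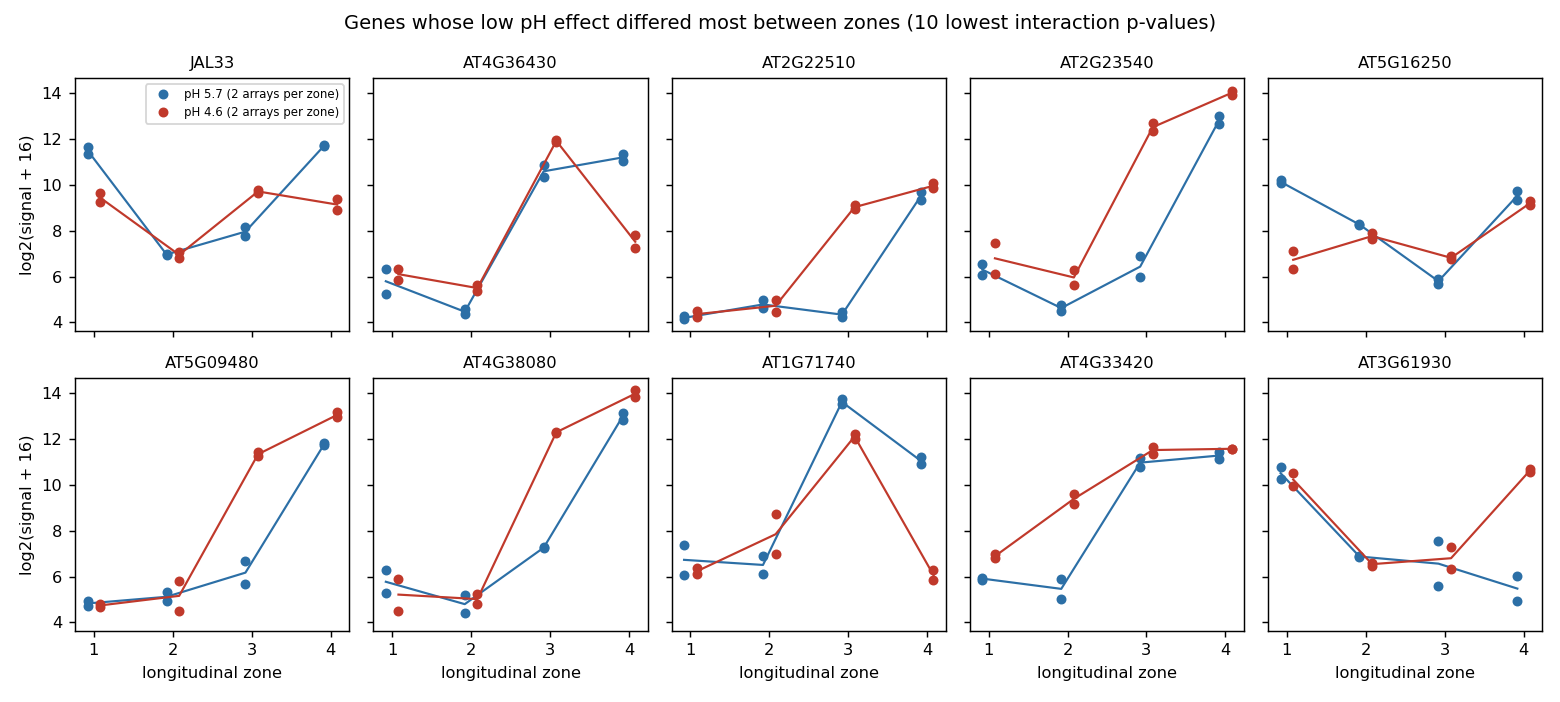
Log2(signal + 16) along the 4 zones for the 10 genes with the lowest interaction p-values, with each array as a point and lines through the means of 2 arrays (blue pH 5.7, red pH 4.6). AT2G22510, AT2G23540, AT5G09480 and AT4G38080 rose from zone 3 to zone 4 at pH 5.7 and were already high in zone 3 at pH 4.6, whereas AT1G71740 fell by 4.99 in zone 4.

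**Figure D3:**
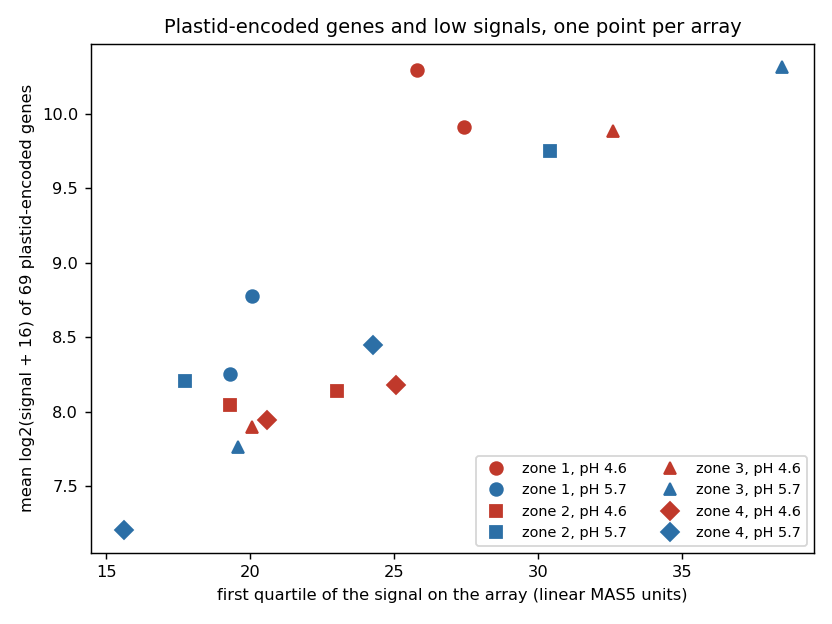
Mean log2(signal + 16) of 69 plastid-encoded genes against the first quartile of the signal, with 1 point per array (colour, pH; shape, zone). Both zone 1 arrays at pH 4.6 (9.91 and 10.29) and 1 array each of zone 2 at pH 5.7 (9.75), zone 3 at pH 4.6 (9.89) and zone 3 at pH 5.7 (10.31) lay above the other 11, which had 7.21 to 8.78.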

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

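Some tests below were chosen after the result they address was seen: the zone 3 test against the gradient towards zone 4 only, and both tests of a raised floor of low signals. The match of mean profiles and the relation to the ubiquitin ratio are not counted among tests written down beforehand. Nor is the comparison of the zone 3 replicate difference with the steps next to zone 3 at low pH. The use of single-array pairings to read the gradient values was likewise not part of the written limits. The remaining tests here were written down beforehand.

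The low pH effect differed between zones for 261 probe sets. The lowest adjusted p-values of the limma F-test belonged to the lectin gene JAL33 (0.000235), the peroxidase AT4G36430 (0.000702), AT2G22510 (0.000702), AT2G23540 (0.000702), AT5G16250 (0.000702), AT5G09480 (0.000702), AT4G38080 (0.000906), AT1G71740 (0.00134), the peroxidase AT4G33420 (0.00134) and AT3G61930 (0.0026). A further 26 genes ranked in a low pH comparison passed the same test, as did 10 list members, among them EXPA18, AT4G26010, UGT72E1 and GSTU28.

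AT2G23540, AT4G38080 and AT5G09480 rose in zone 3 at pH 4.6 and from zone 3 to zone 4 at pH 5.7, but these comparisons share the zone 3 arrays at pH 5.7, so low values there raise both. Sections holding tissue from further up the root at pH 4.6 would give effects correlated with the gradient across probe sets, which are not independent replicates. For the Pearson r values with a gradient below, the effect and the gradient share no array. Pearson r was 0.0719 in zone 1 (single-array pairings -0.0406 to 0.169) and 0.174 in zone 2 (-0.0845 to 0.387). It was 0.0776 in zone 3 against zone 4 minus zone 2 (-0.0137 to 0.14) and -0.0648 in zone 4 (-0.2 to 0.131). By the limits on r written beforehand, the zone 2 value went with a shifted section and the zone 4 value against it. Zones 1 and 3 lay in between. Those limits did not cover the single-array pairings, which in every zone ran from below the lower limit to above the upper one. With that spread these values cannot decide. Against zone 4 minus zone 3, Pearson r was 0.255 in zone 3 (0.0667 to 0.37), a value that a shifted section could give. A deviation common to both zone 3 arrays at pH 5.7 could also give it, since 1 of them stood on each side. By mean profile, zone 3 at pH 4.6 had r = 0.923 with zone 4 and 0.909 with zone 3 at pH 5.7. The other zones at pH 4.6 had their highest r with the same zone. Replicates at pH 5.7 correlated with r = 0.838 in zone 3 and 0.941 in zone 4, and such noise lowers any r with the zone 3 mean. The order of the 2 zone 3 values therefore cannot show a greater likeness to zone 4. Of the 675 probe sets with the same sign in all zones, 13.5% had gradients of that sign in every zone, against 10.5% of all tested. Most of them thus lacked the gradient signs that a shift up the root in every zone needs. Here the gradients of zones 1 and 4 shared pH 5.7 arrays with the effect, which favours agreement in zone 1 and disagreement in zone 4. Noise in the sign of any 1 gradient also lowers the share, so it does not exclude such a shift. The gradients of zones 2 and 3 spanned both neighbouring zones, and shifts down the root or in different directions by zone were not tested. Among 100 splits of the arrays within zones, of 648 distinct ones, 1 reached the 995 probe sets of the mean effect, which was the real one. The highest other had 219 and the median other 0. Each zone was split on its own, so the splits cannot address roots or cultures shared across zones.

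Plastid and mitochondrial transcripts had higher values in zone 1 at pH 4.6. Over the 8 groups the replicate gap in the plastid mean followed the gap in the log2 first quartile of signal, with r = 0.926 (exact permutation p = 0.00243), rho = 0.905 (exact p = 0.00456), r = 0.908 without the 2 farthest groups and a Benjamini-Hochberg value of 0.00365 over 3 relations. With the gap in the ubiquitin 3' to 5' ratio, a measure of RNA quality, it had r = 0.650 (exact permutation p = 0.0862), rho = 0.714 (exact p = 0.0576), r = 0.328 without the 2 farthest groups and a Benjamini-Hochberg value of 0.0862, so RNA quality is not excluded. The plastid mean and the first quartile thus varied together across arrays, and whatever raised both could have produced much of this rise. What raised both was not tested. Each r above depends on which replicate was numbered 1, and the labels do not say what the numbers mean. The exact p-values and the SE below treat the 8 gaps as independent, which roots shared between zones would breach. In zone 1 at pH 4.6 the first quartiles were 27.4 and 25.8 in signal units, above those at pH 5.7. The plastid means there were 9.91 and 10.29 on the log2 scale, against 8.25 and 8.78 at pH 5.7. A constant of the size of the quartile rise, added to every signal, would move genes this bright by little. These values argue against an added floor alone as the source of the plastid rise. Beyond what the first quartile predicted (0.99), the zone 1 effect of 1.58 had an excess of 0.59 ± 0.32 SE, which cannot tell a response of zone 1 from none.

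The 2 zone 3 replicates at pH 5.7 lay furthest apart (r = 0.838). Their difference had r = -0.0124 across probe sets with zone 4 minus zone 2 at pH 5.7 and 0.0875 at pH 4.6. With zone 2 minus zone 3 and zone 4 minus zone 3 at pH 4.6 it had r of -0.109 and -0.0182. These values were weak, but zone 4 minus zone 2 misses genes that peak or dip in zone 3. A replicate taken at another position along the root is therefore not excluded. The difference had r = 0.345 with the replicate difference of zone 2 at pH 5.7, so a floor raised on both second replicates may account for part of it. Roots shared by replicates of the same number could give such a value too. Probe sets are not independent replicates.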

How the results depend on the processing

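A fit was added without the 4 wide-gap arrays, those whose plastid mean lay over 1 log2 unit above that of the other replicate of their group, which are replicate 2 of zone 2 at pH 5.7, of zone 3 at both pH values and of zone 4 at pH 5.7. No zone 1 array was among them, and zone 3 was left with 1 array at each pH, so its test draws its spread from other groups. This fit and the fit with the zone 4 numbers crossed were added after the data were seen; the other settings were fixed earlier, and the cause of a moved count was not tested. No ranked gene changed direction in a setting in which it was fitted, and none of the 37 list calls did in the settings in which lists were tested. Ranked genes did lose their call: 21 of 124 without the 4 wide-gap arrays, 16 of 120 with pseudocount 1, 13 of 100 with the arrays of the comparison alone, 12 of 124 with no intensity trend and 8 of 124 with median centring. Means of lists without a call did change sign, such as the list iron deficiency response from zone 2 to zone 3, from 0.14 to -0.16 with pseudocount 1. Lists were not tested with array weights, with no intensity trend, with the 4 arrays alone or with arrays removed. Low pH effect in zone 1 (112 probe sets past the threshold): 61 with median centring, 55 with no intensity trend, 222 with array weights, 49 with the 4 arrays of the comparison alone, 367 without the 4 wide-gap arrays (none of zone 1), and 33 (without pH 5.7 replicate 1) to 309 (without pH 4.6 replicate 2) without 1 array. Low pH effect in zone 2 (63): 26, 121, 119 and 15 in the same settings other than centring, 95 with a replicate block within each zone, and 15 to 44 without 1 array (pH 4.6 replicates 2 and 1). Low pH effect in zone 3 (459): 292 with pseudocount 1, 266 with median centring, 81 with array weights, 63 with the 4 arrays alone, 89 without the 4 wide-gap arrays (1 array against 1), and 93 (without pH 4.6 replicate 1) to 1550 (without pH 5.7 replicate 1). Low pH effect in zone 4 (477): 1381 with array weights, 989 with the 4 arrays alone, 294 without the 4 wide-gap arrays, and 66 (without pH 4.6 replicate 1) to 151 (without pH 5.7 replicate 2). Mean low pH effect over the 4 zones (995): 583 with median centring, and 511 (without zone 4 pH 4.6 replicate 1) to 1444 (without zone 3 pH 5.7 replicate 1). Zone by pH interaction (261): 113 with pseudocount 1, 517 with pseudocount 64, 163 with no intensity trend, 50 without the 4 wide-gap arrays, and 77 (without zone 4 pH 4.6 replicate 1) to 1142 (without zone 3 pH 5.7 replicate 1). With the zone 4 numbers crossed in the block the interaction had 757. Zone 2 against zone 1 at pH 5.7 (515): 828 with array weights, 207 without the 4 wide-gap arrays, and 123 to 338 (without zone 1 replicates 2 and 1). Zone 3 against zone 2 (5008): 2971 with array weights and 2614 with the 4 arrays alone. Zone 4 against zone 3 (1961): 673, 568 and 898 with array weights, the 4 arrays alone and without the 4 wide-gap arrays, and 629 (without zone 4 replicate 1) to 3541 (without zone 3 replicate 1). Gene list shifts: 0 of 37 with an estimated inter-gene correlation (limma camera, 21 of 176 at unadjusted p under 0.05). List calls were also lost in the other settings, such as 3 of 37 with pseudocount 1 (0 gained) and 6 of 37 with no filter on dim probe sets (4 gained). Median centring shifted the typical probe set by -0.15 in zone 1, -0.14 in zone 4 and 0.20 from zone 3 to zone 4. A replicate block over all groups left every count within 1.5 times, and replicate differences at the 2 pH values correlated across probe sets, which are not independent replicates, by r of -0.06, 0.09, 0.35 and -0.25 in zones 1 to 4. Between neighbouring zones at pH 5.7 the replicate differences had r of 0.0448, 0.345 and 0.309, so a pairing within a pH is left open. With a random block within each pH the mean low pH effect over the 4 zones had 715 probe sets and the interaction 372.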

Other observations

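Low pH calls overlapped with the changes between zones at pH 5.7, though not in a single direction. Of 49 probe sets that rose in zone 2, 37 were also higher in zone 3 than in zone 1 at pH 5.7, against 9.48 for independent lists, and 3 were lower. Of 251 that fell in zone 4, 157 were among those that rose from zone 2 to zone 3, against 34.1, such as AT4G13580, AT1G30750 and AT4G02090, and 14 were among those that fell. In zone 1, 28 of 50 risen probe sets rose from zone 2 to zone 3 (6.8 for independent lists) and 28 of 62 fallen ones fell there (10.5). Other overlaps ran against the gradient or both ways. Of 147 that fell in zone 3, 64 were higher in zone 4 than in zone 2 at pH 5.7 (22.4 for independent lists) and 29 were lower (23.7); of 312 that rose, 116 were higher (47.5) and 77 lower (50.4). Of 226 that rose in zone 4, 35 had risen from zone 2 to zone 3 (30.7) and 73 had fallen (38.3). The pairs of comparisons share no array, but they share the fitted spread of each probe set, so probe sets of small spread are called in both. The counts for independent lists are thus a low baseline, and some overlaps exceeded them in both directions.

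The labels do not say where along the root each zone begins and ends, and this decides how a gradient is read. Measured positions of the sections at each pH, or a marker line for cell maturation, would separate a change of maturation at low pH from a shifted section.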
